A study of Homo sapiens with 4 samples.

How the data were processed

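RNA from FaDu cells with TINCR-HA-FLAG or an empty vector, 2 libraries per group, was extracted with an RNeasy kit and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The deposited table holds whole-number counts of reads per Ensembl gene, not normalized, with 1 column per library. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.9a and DESeq2 1.32.0 and the genome build GRCh38, without saying what each was used for. The counting step, its strand setting and the annotation release are not given in the sources used here. If strand was ignored, overlapping and antisense genes share reads. Genes with near-identical copies are uncertain whatever the strand setting, since reads could be shared between the copies. The table has 60649 gene rows and 12 other library columns, which match no sample described here and were not used. The column headers write TINCR where the sample titles carry a longer construct name, so columns were matched on cell line, construct and replicate number. Gene symbols came from a reference table by Ensembl identifier (60507 rows matched) and positions from the GENCODE annotation of GRCh38 (58381 rows matched).

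Groups were taken from the sample titles. Counts were normalized by TMM and filtered with filterByExpr at its default settings, which left 18771 genes, and tested with the edgeR 4.0.16 quasi-likelihood test (robust, with the non-legacy estimate of dispersion) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called. The common biological coefficient of variation was 0.118, and the fit had 2 residual degrees of freedom per gene before pooling of the spread across genes. CPM values are given as mean ± SD over 2 libraries. Total counts ranged from 17069533 to 22331602, at which 3 counts correspond to 0.13 to 0.18 CPM. This covers counting error only, since reads without molecular identifiers are not independent molecules.

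Gene lists, 27 in all, were fixed before the data were examined. A list was tested where at least 5 members passed the filter, which held for 26 lists. The test was camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, repeated with an estimated correlation, and with fry as a self-contained test. With an estimated correlation, camera takes its p-value from the 2 residual degrees of freedom. That repeat has little power over 26 lists, so a call lost in it does not show that a list is unchanged. List p-values were adjusted over the lists. No gene set collection was used.

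The rule for named genes was also fixed before the data were examined. It takes TINCR, then the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 2, an official symbol and groups that do not overlap. It adds up to 4 called members of each list, and up to 2 of the most expressed members of a list with no called member. From the lists with no called member 1 gene rather than 2 is named, a choice made after the values were seen. Some genes that the rule takes are not reported here, although they stayed in every test. Genes named outside the rule were chosen after their values were seen. They are RN7SL1, the genes on chromosome 15 and the further genes of the closing section.

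The edgeR and DESeq2 tests were tested on simulated counts for the 18771 genes with 200 genes changed per round over 5 rounds. edgeR called 55.8% of genes changed by 1.5-fold, 89.3% of those changed by 2-fold and 99.7% of those changed by 4-fold, and 0.099% of unchanged genes. For DESeq2 these were 47.5%, 84.8%, 98.8% and 0.052%. As counts over the 5 rounds, edgeR called 92 unchanged genes beside 187, 299 and 329 changed ones. DESeq2 called 48 beside 159, 284 and 326. In both tests the share of false calls was therefore above the threshold of 0.05, and more so in edgeR. In a simulated list of 30 genes shifted by 1.4-fold, camera called the list in 20 of 20 rounds and 0 of 520 unchanged lists. The simulated genes varied independently, so this does not measure false calls in lists whose members vary together. In the data the estimated correlation reached 0.96 for the replication-dependent histones and 0.91 for the mitochondrial-encoded transcripts.

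Alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, RLE size factors or library totals in place of TMM, no filter on low counts beyond 1 count in any library, a minimum of 1 CPM in 2 libraries, TINCR left out of the counts, the replicate number as a block, the legacy dispersion estimate and leaving out each library in turn. With a library left out, the lone library of its group is assumed to vary like the other group. The estimated correlation was a repeat named in the design of the list test and not one of these fixed alternatives. Leaving out the genes of 8 chromosomal runs was added after seeing the data. Those runs are the 8 non-overlapping runs of 21 neighbouring genes with the median log2 fold change farthest from 0, over genes with a mean log2 CPM of at least 2. The run length and the number of runs are arbitrary. A first scan used a slightly shorter run and fewer shuffles, and it gave the same regions on chromosomes 15, 5, 2 and 11 but another region on chromosome 9. Figures were drawn with matplotlib 3.10.9.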

Results

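Gene expression was measured by RNA sequencing in FaDu cells, an established line from a human squamous cell carcinoma of the hypopharynx. The cells carried either a construct that overexpresses TINCR joined to the HA and FLAG epitope tags or an empty vector. Each group had 2 libraries, 4 in all. The series describes the replicates as technical, so single-gene and fry p-values measure only the spread between these libraries, which may be technical. Camera p-values with the preset correlation rest on the spread between genes, and the permutation p on random draws of genes. Neither measures the spread between libraries. The counts summed to 17069533 and 17315648 in the empty vector libraries and to 18151424 and 22331602 in the TINCR-HA-FLAG libraries. Mitochondrial genes took 9.43% and 7.58% of the counts with the empty vector and 11.4% and 8.66% with TINCR-HA-FLAG. Against counting error alone, the chi-square per degree of freedom was 12.04 between the empty vector libraries and 16.6 between the TINCR-HA-FLAG libraries. Separate preparations of one RNA could give such values too, so they do not tell technical from biological replicates. Each library was entered as 1 sample.

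The series has 1 comparison, which asks how gene expression in FaDu cells differs when tagged TINCR is overexpressed. TINCR itself was the first gene examined. TINCR was first described as a long RNA induced during terminal differentiation of keratinocytes, and the reference annotation lists it as a protein-coding gene (ENSG00000223573.7, GRCh38 chromosome 19, 5558167 to 5578349, minus strand). It had 68 and 64 counts in the empty vector libraries and 1921 and 2943 counts in the TINCR-HA-FLAG libraries. Scaled to library size (CPM) this was 3.87 ± 0.14 (SD, n = 2) against 118 ± 20.04 (SD, n = 2). The rise was 30.6-fold, a log2 fold change of 4.93 with a standard error of 0.17 (adjusted p = 7.2e-07, edgeR quasi-likelihood test). The counts do not tell reads of the construct from reads of the cell's own gene.

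Of 18771 genes tested, 85 rose and 18 fell with TINCR-HA-FLAG at an adjusted p under 0.05 in edgeR. Among them, 47 rose and 6 fell by at least 2-fold. Both libraries of one group lay above both of the other for each of the 103 genes, as they did for 39.6% of all genes tested. The number of calls depended on single libraries. It was 69 higher and 55 lower without empty vector replicate 1, and 127 and 45 without empty vector replicate 2. It was 171 and 61 without TINCR-HA-FLAG replicate 1, and 226 and 160 without TINCR-HA-FLAG replicate 2. DESeq2 called 108 higher and 44 lower, and 102 of the 103 edgeR calls were among them. With no filter on low counts, 37168 genes were tested and 53 of the 103 calls remained.

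**Figure D1:**
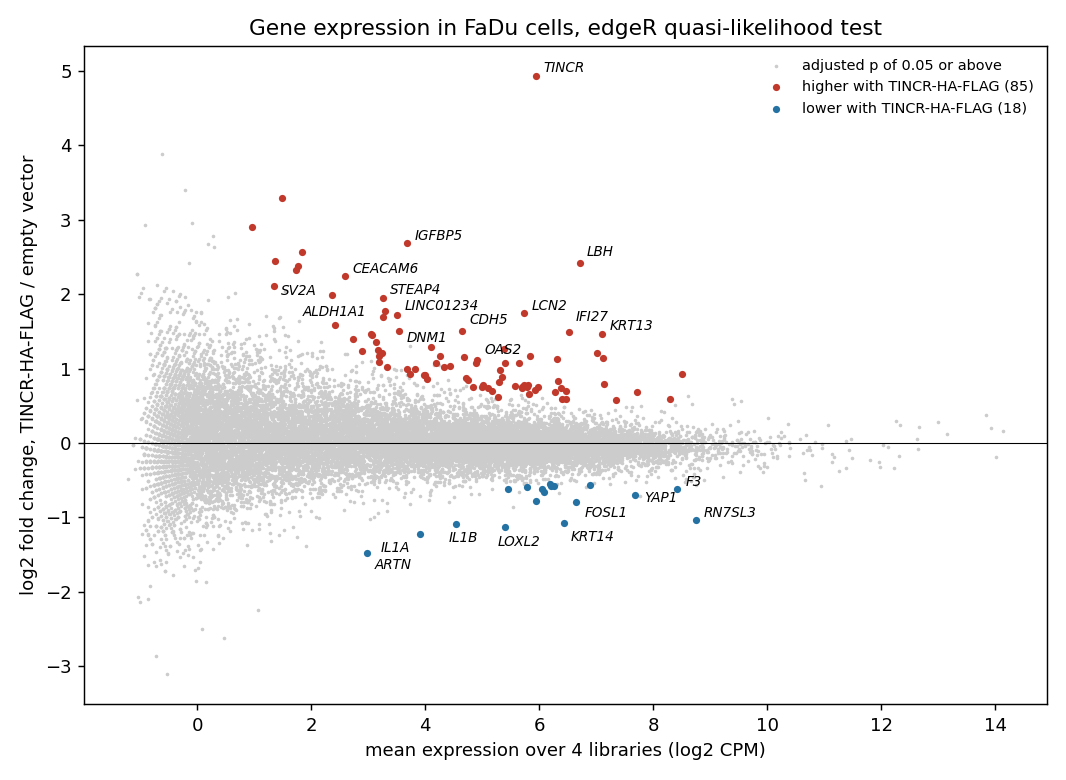
Each point is 1 of 18771 genes; the horizontal axis is mean expression over the 4 libraries (log2 CPM) and the vertical axis the log2 fold change, TINCR-HA-FLAG over empty vector. Red points are the 85 genes that rose and blue points the 18 that fell at an adjusted p under 0.05; TINCR stands highest at 4.93, and a subset of the genes in the text is labelled.

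The largest rises after TINCR, among genes with a mean log2 CPM of at least 2, were in genes of several functions. IGFBP5, which encodes a binding protein for insulin-like growth factors, rose from 3.37 ± 0.18 to 21.8 ± 2.16 CPM (SD, n = 2 per group). Its log2 fold change was 2.68 (SE 0.19, adjusted p = 0.00027). LBH, which encodes a transcription cofactor, rose from 32.9 ± 7.63 to 175 ± 15.01 CPM (SD, n = 2 per group; log2 fold change 2.41, SE 0.15, adjusted p = 0.00014). The adhesion glycoprotein gene CEACAM6 rose by a log2 fold change of 2.24, the synaptic vesicle gene SV2A by 1.99 and the metalloreductase gene STEAP4 by 1.95. ALDH1A1, a retinaldehyde dehydrogenase gene, rose by 1.78, and LCN2, which encodes a siderophore-binding lipocalin, by 1.74. The noncoding RNA LINC01234 rose by 1.71, and SPTSSB, which encodes a small subunit of serine palmitoyltransferase, by 1.69. MGAM, which encodes maltase-glucoamylase, rose by 1.59, the dynamin gene DNM1 by 1.51 and CDH5, which encodes vascular endothelial cadherin, by 1.501. Standard errors of these 10 changes lay between 0.14 and 0.27, and edgeR adjusted p between 0.00052 and 0.033. The call of MGAM was lost without empty vector replicate 1 (adjusted p = 0.056). CEACAM6 and MGAM have similar paralogs with which reads could be shared.

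The largest fall was in ARTN, which encodes the neurotrophic factor artemin, from 11.6 ± 0.29 to 4.16 ± 0.36 CPM (SD, n = 2 per group; log2 fold change -1.48, SE 0.20, adjusted p = 0.011). The interleukin 1 genes IL1A and IL1B had log2 fold changes of -1.23 (SE 0.16, adjusted p = 0.0082) and -1.09 (SE 0.13, adjusted p = 0.0047). LOXL2, a lysyl oxidase gene of the extracellular matrix, changed by -1.14 and the basal keratin gene KRT14 by -1.08, where keratins of similar sequence could share reads. The AP-1 gene FOSL1 changed by -0.80, the tubulin gene TUBA4A by -0.79 and YAP1, the transcriptional effector of the Hippo pathway, by -0.70. The homeobox gene IRX2 changed by -0.65, the tissue factor gene F3 by -0.62 and the centrosomal gene CEP72 by -0.62. RN7SL3, an RNA of the signal recognition particle, changed by -1.04. That value is uncertain, because the near-identical RN7SL1 had a log2 fold change of -0.19 (SE 0.20, adjusted p = 0.83). The call of YAP1 was lost without empty vector replicate 2 (adjusted p = 0.069), as was that of IRX2 (adjusted p = 0.13). The call of F3 was lost without empty vector replicate 1, without empty vector replicate 2 and without TINCR-HA-FLAG replicate 1 (adjusted p = 0.18, 0.12 and 0.058). With no filter on low counts, FOSL1, TUBA4A, YAP1, IRX2, F3, CEP72 and MGAM were no longer called (adjusted p from 0.059 to 0.13).

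Genes of the cornified envelope and terminal differentiation were not called as a list. Of the 52 genes of the cornified envelope and terminal differentiation list, 22 passed the filter on low counts. KRT13, a keratin of the suprabasal layers of non-cornifying stratified epithelium, rose from 73.2 ± 7.34 to 202 ± 19.5 CPM (SD, n = 2 per group; log2 fold change 1.47, SE 0.12, adjusted p = 0.00057). It was the 1 member called over all genes tested, against 3 adjusted over the list alone, and the median of the list was 0.05 (camera adjusted p = 0.53). In the list of basal layer and hemidesmosome genes, KRT14, ITGA6 and CD44 fell and SOX2 rose, among 20 tested, with 5 lower and 1 higher when adjusted over the list alone. ITGA6, the integrin subunit of hemidesmosomes, changed by -0.58 (SE 0.10, adjusted p = 0.046), and CD44, a hyaluronan receptor gene, by -0.57 (SE 0.11, adjusted p = 0.049). SOX2, a transcription factor gene of squamous progenitors, rose by 1.03 (SE 0.18, adjusted p = 0.041). The basal list as a whole was called lower (median -0.15, camera adjusted p = 0.0063), but adjusted p = 0.66 with an estimated correlation. That call was also lost without empty vector replicate 2 (adjusted p = 0.30) and without TINCR-HA-FLAG replicate 1 (adjusted p = 0.29). The call of CD44 was lost without empty vector replicate 1, without empty vector replicate 2 and without TINCR-HA-FLAG replicate 1 (adjusted p = 0.055, 0.063 and 0.060), and that of ITGA6 without empty vector replicate 2 (adjusted p = 0.13). With no filter on low counts, ITGA6, CD44 and SOX2 were not called (adjusted p = 0.13, 0.15 and 0.11).

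Markers of simple, non-stratified epithelium were higher. Of 10 tested members, 9 had a positive log2 fold change, with a median of 0.57. The list was called higher (camera adjusted p = 0.0025), but adjusted p = 0.66 with an estimated correlation. CEACAM6 and AGR2, a gene of secretory epithelia, passed the test over all genes, and 4 members did when adjusted over the list alone. AGR2 rose from 4.38 ± 1.24 to 12.02 ± 0.81 CPM (SD, n = 2 per group; log2 fold change 1.45, SE 0.23, adjusted p = 0.025). No member was called by edgeR among the transcription factors of keratinocyte differentiation (21 tested, median 0.10, camera adjusted p = 0.071), the enzymes of the lipid barrier (16 tested, median 0.14, camera adjusted p = 0.10) and the epithelial junction genes (30 tested). For the junction genes the median was -0.006 and the mean 0.05, and camera, which gave the direction as higher, had an adjusted p of 0.77. Over the 67 genes of these 3 lists, 5 had an unadjusted edgeR p under 0.05, beside 1913 of all 18771 genes tested. DESeq2 called 1 of the 67. Adjusted over the list alone, 2 junction genes and no member of the other lists passed. NOTCH1 had 663 ± 39.6 CPM with the empty vector and 671 ± 0.77 with TINCR-HA-FLAG (SD, n = 2 per group). SPTLC1 had 125 ± 6.77 and 140 ± 5.07 CPM, and DSP 764 ± 7.35 and 710 ± 60.7 CPM (SD, n = 2 per group). The differentiation regulators were called higher without empty vector replicate 2 (camera adjusted p = 0.044).

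Interferon-stimulated genes were higher with TINCR-HA-FLAG. All 42 members were tested, 40 had a positive log2 fold change and the median was 0.34. The test passed for 6 members, all higher, over all genes and for 17 when adjusted over the list alone. IFI27 rose from 47.8 ± 0.48 to 134 ± 10.5 CPM (SD, n = 2 per group; log2 fold change 1.49, SE 0.11, adjusted p = 0.00027). The antiviral genes OAS2 and MX1 rose by log2 fold changes of 1.12 (SE 0.12, adjusted p = 0.0041) and 0.98 (SE 0.12, adjusted p = 0.0047). IRF7, which encodes a transcription factor of the interferon response, rose by 0.84 (SE 0.12, adjusted p = 0.016). The list was called higher with the preset correlation (camera adjusted p = 1.8e-12). With an estimated correlation, which was 0.028 here, the list had an unadjusted camera p of 0.026 and an adjusted p of 0.66. It stayed called without each of the 4 libraries in turn. In fry, which does not compare the list with other genes, its adjusted p was 0.075 for a change in one direction and 0.00070 for change in either direction.

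Cytokine and NF-kB genes moved both ways. Of 27 tested, LCN2 and CSF1 rose and IL1A and IL1B fell, with 2 higher and 3 lower when adjusted over the list alone. CSF1, the macrophage colony-stimulating factor gene, rose by 0.76 (SE 0.12, adjusted p = 0.025), a call lost without empty vector replicate 1 (adjusted p = 0.087) and with no filter on low counts (adjusted p = 0.076). The median of the list was 0.24 (camera adjusted p = 0.081), and the list was called higher with DESeq2 statistics (adjusted p = 0.035) and with a minimum of 1 CPM in 2 libraries (adjusted p = 0.048). In the epithelial-mesenchymal transition list (34 tested), TGFB2, a transforming growth factor beta gene, rose by 1.29 (SE 0.16, adjusted p = 0.0066) and LOXL2 fell, with 2 higher and 3 lower adjusted over the list alone. The list median was -0.05 (camera adjusted p = 0.055). Of the 21 tested YAP and TEAD targets, TGFB2 rose and F3 fell, with 3 higher and 2 lower adjusted over the list alone and a median of 0.14 (camera adjusted p = 0.50). In the list of immediate early and AP-1 genes (35 tested), FOSL1 and EREG, an epidermal growth factor family ligand gene, fell, with 1 higher and 4 lower adjusted over the list alone. EREG changed by -0.56 (SE 0.10, adjusted p = 0.048), a call lost without empty vector replicate 1 and without empty vector replicate 2 (adjusted p = 0.067 and 0.083) and with no filter on low counts (adjusted p = 0.14). The list median was -0.08 (camera adjusted p = 0.055). The epithelial-mesenchymal transition and immediate early lists were called lower without empty vector replicate 1 (camera adjusted p = 0.021 and 0.0073), without TINCR-HA-FLAG replicate 2 (0.015 and 0.0028), and under 4 and 3 other settings. Of 34 hypoxia and glycolysis genes tested, VEGFA, the vascular endothelial growth factor gene, fell, and 1 higher and 1 lower passed when adjusted over the list alone. VEGFA changed by -0.59 (SE 0.11, adjusted p = 0.047), a call lost without empty vector replicate 1 (adjusted p = 0.094) and with no filter on low counts (adjusted p = 0.13). The hypoxia list median was -0.11 (camera adjusted p = 0.094), and the list was called lower with DESeq2 statistics (adjusted p = 0.010) and without TINCR-HA-FLAG replicate 2 (adjusted p = 0.027).

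Lists of growth, stress and metabolism had small negative medians. MYC and ribosome biogenesis genes had a median log2 fold change of -0.23, with 30 of 32 negative (camera adjusted p = 2.7e-07). NRF2 targets had a median of -0.20, with 25 of 28 negative (camera adjusted p = 3.7e-05). The unfolded protein and integrated stress response list had a median of -0.15 (camera adjusted p = 0.00099), the heat shock list -0.15 (0.042) and the ubiquitin and proteasome list -0.10 (0.0027). The medians were -0.10 for G1/S and DNA replication (camera adjusted p = 0.0068), -0.10 for cholesterol biosynthesis (0.020), -0.08 for nuclear-encoded oxidative phosphorylation (0.017) and -0.13 for replication-dependent histones (0.0025). With an estimated correlation, these 9 lists had an adjusted p = 0.66, except the histones with an adjusted p = 0.69. G2/M and mitosis genes had a median of -0.06 (camera adjusted p = 0.094) and cytosolic ribosomal proteins -0.05 (camera adjusted p = 0.071). These 2 lists were called lower without empty vector replicate 1 (adjusted p = 0.049 and 0.00025), without TINCR-HA-FLAG replicate 2 (0.019 and 3.9e-05) and with DESeq2 statistics (0.031 and 0.021). The ribosomal list turned positive without empty vector replicate 2 and without TINCR-HA-FLAG replicate 1 (adjusted p = 0.62 and 0.29). No member of these 11 lists was called by edgeR. Of their 395 genes, 49 had an unadjusted edgeR p under 0.05, beside 1913 of all 18771 genes tested. DESeq2 called 3 of the 395, with FTH1 and NCL among them. Adjusted over the list alone, 6 NRF2 targets, 3 MYC and ribosome biogenesis genes and 1 heat shock gene passed, all lower, and none did in the other lists.

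The single genes named here from these lists were not called by edgeR, while DESeq2 called NCL and FTH1 lower (adjusted p = 0.016 for both). The nucleolin gene NCL had 692 ± 16.03 CPM with the empty vector and 503 ± 27.7 with TINCR-HA-FLAG (SD, n = 2 per group; log2 fold change -0.46, SE 0.12, adjusted p = 0.15). The ferritin gene FTH1 had 2361 ± 350.1 and 1578 ± 246 CPM (SD, n = 2 per group; adjusted p = 0.22), and the amino acid transporter gene SLC7A5 1905 ± 259 and 1350.3 ± 276 CPM (adjusted p = 0.34). The chaperone gene HSPA8 had 2473 ± 177 and 2159.9 ± 221 CPM, and the cyclin gene CCND1 1222 ± 68.6 and 1081 ± 37.6. ATP5F1B had 464 ± 39.5 and 400 ± 34.6 CPM, and the histone gene H1-5 474 ± 52.2 and 449 ± 51.7. The proliferation marker MKI67 had 696 ± 53.1 and 715 ± 97.6 CPM, and RPS2 4527 ± 663 and 4362 ± 854. The edgeR adjusted p of HSPA8, CCND1, ATP5F1B, H1-5, MKI67 and RPS2 lay between 0.62 and 0.96. Without empty vector replicate 2 the list calls were lost except for MYC and ribosome biogenesis (adjusted p from 0.085 to 0.82 for the others), and without TINCR-HA-FLAG replicate 1 all were lost (adjusted p from 0.091 to 0.95), with the histones turning positive. Mitochondrial-encoded transcripts moved the other way, with all 13 log2 fold changes positive, a median of 0.24 and no member called by edgeR or adjusted over the list alone. Their list was called higher (camera adjusted p = 0.018), but adjusted p = 0.66 with an estimated correlation, and the call was lost without empty vector replicate 2 (adjusted p = 0.48) and without TINCR-HA-FLAG replicate 1 (adjusted p = 0.68). MT-CO1 had 16896 ± 3260.3 CPM with the empty vector and 18963 ± 4057 with TINCR-HA-FLAG (SD, n = 2 per group; adjusted p = 0.89).

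**Figure D2:**
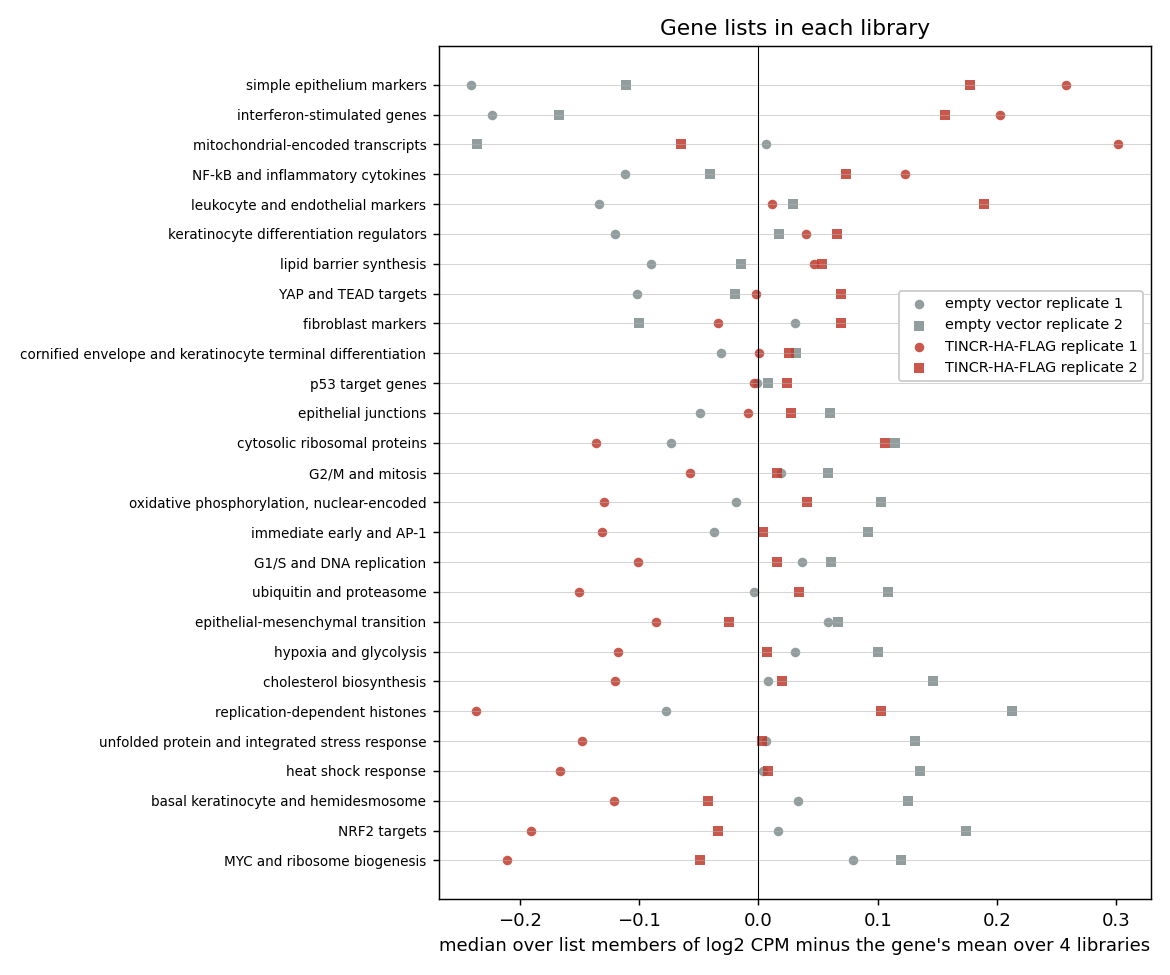
Each row is 1 of 27 gene lists; the horizontal axis is the median over its tested members of log2 CPM minus each gene's mean over the 4 libraries, with grey for the empty vector, red for TINCR-HA-FLAG, circles for replicate 1 and squares for replicate 2. Interferon-stimulated genes lie at -0.22 and -0.17 with the empty vector and at 0.20 and 0.16 with TINCR-HA-FLAG, while for mitochondrial-encoded transcripts empty vector replicate 1 (0.007) lies above TINCR-HA-FLAG replicate 2 (-0.07).

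In all, camera with a preset correlation called 13 of 26 lists, 10 lower and 3 higher. With an estimated correlation it called 0, with 1 list, the interferon-stimulated genes, at an unadjusted p under 0.05. At 2 residual degrees of freedom that repeat has little power, so it does not show that the lists are unchanged. Fry called 0 lists in one direction, with 3 at an unadjusted p under 0.05, and 11 for change in either direction. Of 27 tested p53 target genes none was called by edgeR and 1 was higher when adjusted over the list alone (median 0.05, camera adjusted p = 0.67); CCNG1, a cyclin gene among them, had 106 ± 7.17 and 113 ± 8.01 CPM (SD, n = 2 per group). Among markers of other cell types, none of 8 fibroblast genes was called by edgeR and 2 were higher when adjusted over the list alone (median 0.08, camera adjusted p = 0.68). FBLN1 had 249 ± 31.3 and 332 ± 20.99 CPM (SD, n = 2 per group; adjusted p = 0.23). Over the 48 genes of the p53, fibroblast and mitochondrial lists, 8 had an unadjusted edgeR p under 0.05, and DESeq2 called 0. Over all 18771 genes tested, 1913 had an unadjusted edgeR p under 0.05. Of 14 leukocyte and endothelial genes 4 passed the filter on low counts, too few for a list test, and CDH5 was the 1 called, also when adjusted over the list alone.

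Called genes lay close together on chromosome 15. The following genes were chosen after their values were seen. Between 88636153 and 90935196 on GRCh38, 11 genes rose and none fell, and 15 further genes with a mean log2 CPM of at least 2 were not called. ARPIN, an inhibitor of the Arp2/3 complex, rose by a log2 fold change of 1.21 (SE 0.11, adjusted p = 0.0011), AP3S2, an adaptor complex subunit gene, by 1.16 (SE 0.13, adjusted p = 0.0044) and IDH2, which encodes mitochondrial isocitrate dehydrogenase, by 1.13 (SE 0.13, adjusted p = 0.0047). ISG20, a member of the interferon list, rose by 1.39 (SE 0.23, adjusted p = 0.030). The remaining 7 were SEMA4B, MFGE8, ABHD2, ZNF710, CRTC3, HDDC3 and the noncoding RNA MIR9-3HG. ZNF710 and CRTC3 overlap antisense genes, from which reads cannot be told apart where the counting ignored strand. The 15 uncalled genes all had positive log2 fold changes, from 0.08 to 0.81 with a median of 0.49. Uncalled genes within 5 Mb had a median of 0.07 on the lower side (13 genes) and -0.11 on the upper side (8 genes).

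**Figure D3:**
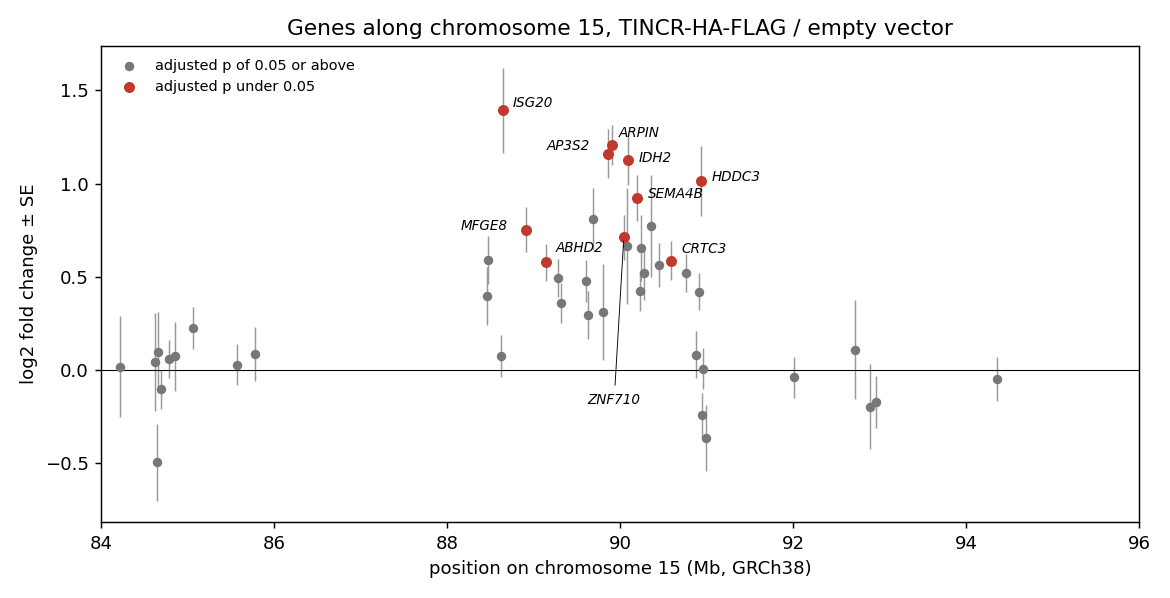
Points are 46 genes with a mean log2 CPM of at least 2 between 84 and 96 Mb of chromosome 15 (GRCh38), placed at the gene's midpoint; the vertical axis is the log2 fold change, TINCR-HA-FLAG over empty vector, with bars of 1 standard error. The 10 red points are called genes with gene names, all above 0.5, and the grey points between them are all above 0, whereas those on both sides lie around 0.

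Neighbouring genes also moved together elsewhere. Over runs of 21 neighbouring expressed genes, the median log2 fold change was -0.50 on chromosome 5 between 0.44 and 6.67 Mb, where all 21 were negative and CEP72 and IRX2 lie. It was between -0.34 and -0.41 in 4 runs on chromosome 2 between 215 and 242 Mb, where TUBA4A and IGFBP5 lie, and -0.37 on chromosome 11 between 100.7 and 107 Mb, where YAP1 lies. A run on chromosome 9 that holds ALDH1A1 had a median of 0.32. IGFBP5 rose although its neighbours had a negative median. The 8 runs held 15 of the 103 called genes (14.6%) and 1.52% of the genes tested. As the runs were picked from the same libraries for a median far from 0, such an excess is largely built in. Without the genes of these runs, an alternative chosen after seeing the data, 62 genes were higher and 8 lower, of which 36 and 6 by at least 2-fold. The lower calls inside the runs were CEP72, IRX2, TUBA4A and YAP1. Calls lost outside the runs were lost because unchanged p-values were adjusted again over the remaining genes.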

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

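The TINCR log2 fold change, 4.93, stayed past the threshold under all its alternatives, between 4.74 (without TINCR-HA-FLAG replicate 2) and 5.10 (without TINCR-HA-FLAG replicate 1). The estimated correlation is a repeat of the list test named in its design but not among the fixed alternatives, and leaving out the genes of the chromosomal runs was chosen after seeing the data. Named genes in this part are those taken by the naming rule, as no others were refitted by name. Except where a reason is given, the cause was not tested.

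With no filter on low counts the calls went from 85 to 47 higher and from 18 to 6 lower, with more genes in the adjustment, and 13 named genes lost their call. The cholesterol, mitochondrial-encoded and heat shock lists also lost theirs (adjusted p = 0.051, 0.051 and 0.082). Without the genes of the chromosomal runs 8 were lower, in part because p-values were adjusted again over the remaining genes. DESeq2 called 44 lower, and with its statistics the ribosomal protein (adjusted p = 0.021), epithelial-mesenchymal transition (0.033), G2/M (0.031), hypoxia (0.010), immediate early (0.0096) and NF-kB (0.035) lists passed. With library totals the epithelial-mesenchymal transition (0.049) and immediate early (0.050) lists passed. With a minimum of 1 CPM in 2 libraries those lists (0.042 and 0.048), the differentiation regulators (0.048) and the NF-kB list (0.048) passed. NOTCH1, not called, had a log2 fold change of -0.0065 with DESeq2 and -0.0022 with RLE size factors, against 0.02. With an estimated correlation the 13 list calls were lost (adjusted p = 0.66, and 0.69 for the histones), in a test with little power at 2 residual degrees of freedom.

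With the replicate number as a block 2633 genes were called, 1317 higher and 1316 lower, of which 242 and 60 by at least 2-fold, and the 103 calls were among them. The block leaves fewer residual degrees of freedom than the 2 of the main fit, so these calls rest on less information about the spread. Under the block the ribosomal protein and epithelial-mesenchymal transition lists passed (adjusted p = 0.046 for both), and it ended no call of a named gene or list. It also called 8 named genes that were otherwise not called by edgeR, ATP5F1B, CCND1, FTH1, HSPA8, NCL and SLC7A5 lower and FBLN1 and MT-CO1 higher. Deviations of same-numbered libraries from their group means correlated at 0.37 across genes. With 2 pairs, and no label that ties a number to a shared day or culture, the libraries share only a number by their labels. Log2 CPM correlated at 0.9866 between the libraries numbered 2 and at 0.9850 between those numbered 1. Within groups it correlated at 0.9859 (empty vector) and 0.9864 (TINCR-HA-FLAG). Whether same-numbered libraries were prepared together stays open.

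Without each library in turn, with fewer libraries in the fit, higher calls ranged from 69 to 226, lower calls from 45 to 160, higher calls of at least 2-fold from 45 to 99 and lower ones from 11 to 20. These fits shared 69 (without empty vector replicate 1) to 102 (without TINCR-HA-FLAG replicate 2) of the 103 calls. Adjusted p of lists called lower ranged from 0.0047 to 0.30 for basal keratinocyte genes, from 0.0013 to 0.69 for cholesterol, from 0.00044 to 0.68 for G1/S, from 0.0042 to 0.95 for heat shock, from 6.3e-08 to 0.091 for MYC, from 8.7e-06 to 0.12 for NRF2, from 0.00047 to 0.78 for oxidative phosphorylation, from 9.8e-08 to 0.82 for histones, from 2.2e-05 to 0.78 for ubiquitin and proteasome and from 4.4e-05 to 0.29 for the unfolded protein response. For mitochondrial-encoded transcripts the range was 0.0012 to 0.68. For lists not called it was 0.67 to 0.88 for the cornified envelope, 3.9e-05 to 0.62 for ribosomal proteins, 0.34 to 0.71 for junctions, 0.015 to 0.56 for epithelial-mesenchymal transition, 0.51 to 0.88 for fibroblasts, 0.019 to 0.82 for G2/M, 0.027 to 0.78 for hypoxia, 0.0028 to 0.78 for immediate early genes, 0.044 to 0.76 for differentiation regulators, 0.56 to 0.71 for p53 targets and 0.38 to 0.9995 for YAP targets. Directions turned in at least 1 of these fits for the cornified envelope, ribosomal protein, junction, fibroblast, p53, YAP and histone lists. The interferon and simple epithelium lists stayed called in all 4. Among uncalled named genes the log2 fold change ranged from -0.016 to 0.17 for CCNG1, from -0.23 to 0.04 for H1-5, from -0.10 to 0.17 for MKI67, from -0.064 to 0.36 for MT-CO1, from -0.083 to 0.084 for NOTCH1 and from -0.27 to 0.14 for RPS2. None of the called genes taken by the naming rule changed direction under the alternatives in which it was tested.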

Other observations

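The genes in this part were chosen after their values were seen. Several genes with low counts in the empty vector libraries rose by more than 2 on the log2 scale. HMCN1, an extracellular matrix gene, rose from 0.47 ± 0.34 to 4.75 ± 1.88 CPM (log2 fold change 3.30, edgeR adjusted p = 0.029), and the gluconeogenic enzyme gene FBP1 from 0.41 ± 0.003 to 3.08 ± 0.67 CPM (2.90, adjusted p = 0.031). The bone morphogenetic protein gene BMP3 rose from 1.03 ± 0.05 to 5.44 ± 1.52 CPM (2.38, adjusted p = 0.025; SD, n = 2 per group throughout). Among genes with higher counts, IGFBP3 rose from 86.4 ± 12.2 to 191 ± 1.43 CPM (adjusted p = 0.0027), the complement gene C3 from 32.0 ± 4.26 to 67.7 ± 6.74 CPM (adjusted p = 0.0051) and the ceruloplasmin gene CP from 35.0 ± 0.09 to 79.1 ± 15.3 CPM (adjusted p = 0.0047). SLC20A1, on chromosome 2 beside IL1A and IL1B, fell from 79.6 ± 8.05 to 52.0 ± 0.52 CPM (adjusted p = 0.047).

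Of the tests reported from here on, those of chance placement, chance order, library pairs (interferon list and lower runs), equal shifts and replicate differences were chosen only after the result, or one closely tied to it, was seen. The chromosome 15 cluster had been noticed from its called genes before its uncalled genes were examined.

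Retinoid genes were among the calls. RARB, a retinoic acid receptor gene, rose by a log2 fold change of 1.46 (SE 0.23, adjusted p = 0.025), the retinol dehydrogenase gene RDH10 by 1.03 (SE 0.13, adjusted p = 0.0074) and ALDH1A1 by 1.78. The hypothesis that retinoic acid pathway genes changed together was tested on 22 further members of a retinoid list. Of these, 10 were positive and 1, the reductase gene DHRS3, was called (0.77, SE 0.13, adjusted p = 0.029), and their median of -0.04 lay at percentile 24.5 of 10000 random lists matched on expression. The test argues against a shift of the pathway as a whole.

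Runs of neighbouring genes moved together on chromosomes 15, 5, 2 and 11, and a candidate explanation is that the TINCR-HA-FLAG and empty vector populations differ in copy number there. On chromosome 15 the uncalled genes had a median of 0.49, at percentile 99.97 of 11520 runs of as many neighbouring genes, which meets what a copy number difference predicts there. In the runs that were lower all library pairs had negative medians, -0.20 or below, but these runs were picked from the same libraries for a median far from 0, which nearly builds this in, so copy number stays open there. Reads shared among called genes are argued against, as the 11 called genes of the chromosome 15 span overlap no other called gene. Reads shared with uncalled genes were not tested, and ZNF710 and CRTC3 overlap uncalled antisense genes. Chance placement is argued against, as 0 of 10000 random draws placed as many within 5 Mb (permutation p = 1e-04, the smallest they can give). So is chance order, as 1 of 1000 shuffles of gene order had a run as far from 0 as the least extreme of the 8. Whether every gene of the span shifted equally stays open. The SD of 0.29 over 15 well-expressed genes was more than 2 times their median standard error of 0.11. That error is between libraries that may be technical, and the span was chosen for its called genes, so this cannot decide. Copy number also stays open, as 1 population per vector confounds it with the construct. So does regional regulation, which was not tested.

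Interferon-stimulated genes were higher in both TINCR-HA-FLAG libraries than in both empty vector libraries. A single outlying library is argued against, since the lowest of the 4 medians over library pairs was 0.33. Of the 42 members 1, ISG20, lies in the chromosome 15 span, and the median without it was 0.32, or 0.917 of the full median, but leaving out 1 member can hardly move a median, so an effect of the span on the other members stays open. A response of the cells to the construct or to its introduction, and a difference between the populations that predates it, stay open and were not tested.

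The growth, stress and metabolism lists called lower may reflect variation between libraries that is also present within the groups. Of the 10 lists called lower, 7 had a difference between replicates of a group at least as large as the difference between the groups, and 5 had both libraries of one group below both of the other. The MYC and ribosome biogenesis, NRF2 and basal keratinocyte lists are those with the larger difference between groups, so an effect of TINCR-HA-FLAG on them stays open. In all 10 lists replicate 1 lay below replicate 2 in both groups. Each TINCR-HA-FLAG library also lay below the empty vector library of the same number. An effect on the other 7 lists is therefore not excluded, although no label ties a number to a shared preparation.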
